A study of Arabidopsis thaliana with 27 samples.

How the data were processed

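Transcript levels were measured in callus of Arabidopsis thaliana with Affymetrix arrays, 1 array per RNA sample. Hypocotyl pieces had first spent 6 days on medium that induces callus, and RNA was taken 0, 3 or 6 days after the callus was moved to medium that induces shoots. The 27 arrays fall into 9 groups of 3, which combine these times with 3 genotypes: wild type Columbia, the UPF1 mutant that the labels name lba1-1/upf1-1 (here upf1-1) and the UPF3 mutant upf3-1. Groups and replicate numbers were taken from the sample labels. Part of the title of upf1-1 day 0 replicate 1 says wild type, while its source name and genotype say upf1-1. It was kept in upf1-1, and its nearest array in the deposited values was another array of that group. The series' design text names 0 and 3 days only, and the sample labels were followed for day 6. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

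The deposited values are log2 signals per probe set made by the authors with RMA (robust multi-array average), per the submitters' processing notes, and the version of RMA is not given in the sources used here. RMA subtracts a background, forces every array onto the same distribution of probe signals and summarises the probes of a set, so a change shared by most transcripts cannot be seen in these values. The 27 columns had the same median of 6.57 and, when sorted, differed by at most 0.00758. A second deposited table of the same arrays held the same log2 values, with 0 values that differed, so the use of that table in place of the other gave no separate result. Values ran from 2.04 to 13.48. The number of arrays limits the precision: log2 values of 2 replicates of a group differed with an SD of 0.165 to 0.282 over probe sets (median 0.208).

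The arrays hold 22810 probe sets, of which 64 are controls. The probe set annotation gave 1 gene symbol for 13513 probe sets, several for 503 and none for 8794. Probe sets with several symbols or none were not named and not used for single genes. Of the 13513, 13436 were matched to a locus of a RefSeq gene table (assembly TAIR10.1), which was used only for names, gene types and neighbours. The build behind the annotation is not named, so no coordinates are given. A gene with more than 1 probe set (144 genes) was represented by the one with the highest mean over all arrays, which left 13286 genes. Of these, 275 rest on probe sets whose suffix marks possible cross-hybridisation, and 1535 carry a symbol other than the locus.

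Differences were tested with limma (version 3.58.1, in R 4.3.3; statmod 1.5.0 and jsonlite 2.0.0 were loaded too). A linear model with 1 mean per group was fitted to all 27 arrays with lmFit and eBayes, so that the 9 groups share an estimate of the spread, and 15 contrasts were taken from it. These are day 3 and day 6 over day 0 in the wild type, each mutant over the wild type on each day, the difference between mutant and wild type in the change from day 0 to days 3 and 6, and upf3-1 over upf1-1 on each day. Tests were two-sided with Benjamini-Hochberg adjustment over the 13286 genes of a contrast, and a gene is called when the adjusted p is under 0.05. Log2 fold changes are given with the standard error (SE) of the model and rest on 3 arrays per group. The procedure was tested on simulated data shaped like the comparison of upf1-1 with wild type on day 0, with 200 of 13286 genes changed. It recovered 57 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 8 false calls, and made 0 calls in an unchanged comparison.

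The groups, the tests, the alternatives, 20 gene lists and the rule for genes to be named were chosen before the data were examined. The rule takes UPF1 and UPF3 in every array, the 6 highest and 6 lowest log2 fold changes among called genes whose 3 and 3 arrays do not overlap, for each list up to 4 called members with the largest change (or the 2 with the smallest p where none is called), the 10 genes with the largest mean change among those called in the same direction in both mutants on all 3 days, and the 3 highest and 3 lowest called genes of the remaining contrasts. The probe set annotation used here names no probe set for UPF1, which was therefore not analysed here. Of 322 list members, 63 were measured by a probe set with 1 symbol. Measured members numbered 4 of 10 for factors of nonsense-mediated mRNA decay (NMD) and the exon junction complex (1 more was dropped because its symbol did not match its locus), 6 of 15 for reported NMD targets, 10 of 21 for genes with a conserved upstream open reading frame (uORF), 8 of 22 for early auxin response, 1 of 14 for auxin transport and synthesis, 2 of 19 for cytokinin response, 4 of 28 for shoot meristem and leaf primordium, 4 of 16 for root meristem and root cell types, 6 of 25 for photosynthesis and greening, and 2 of 23 for cell cycle and DNA replication. They numbered 3 of 5 for the stomatal lineage, 3 of 12 for anthocyanin synthesis, 2 of 9 for sugar, starvation and abscisic acid (ABA) response, 1 of 23 for salicylic acid and immune response, 2 of 17 for NLR immune receptors, 1 of 14 for jasmonate and ethylene defence, and 4 of 7 for reference genes. The lists of splicing regulators (0 of 23), xylem and phloem (0 of 12) and hypoxia (0 of 7) had no measured member and gave no result.

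The 10 lists with at least 3 measured genes (a minimum set after the coverage was known and before any value was used) were tested in each contrast with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over 150 tests. Camera compares a list with all other genes, and fry asks only whether the genes of a list move, on balance, one way. Camera at the preset correlation called 29 of the 150 tests, of which 19 were also called with an estimated correlation, and fry called 45. List counts are given over all genes tested, and many of those that differ when adjusted over the list alone are given too. Adjustment over the list alone was made within 1 list and contrast, not over lists or contrasts. For the lists with 1 measured member (YUC4, SAG101 and PDF1.2) it leaves the p-value unadjusted. UPF3 stands in 2 lists, of NMD factors and of reported NMD targets, and AT5G40920 stands in those of NMD targets and NLR receptors.

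Agreement of the mutants was measured by Pearson's r and covariance of log2 fold changes and by the overlap of called genes. Both mutants are compared with the same wild type arrays, so these values were also computed for 100 simulated pairs of unchanged mutants sharing those arrays. Other settings fixed beforehand were the replicate number as a block, leaving out dim genes (under the 30th percentile of the mean) or cross-hybridising probe sets, the mean of a gene's probe sets, all probe sets, centring each array on 4 reference genes, eBayes with trend and robust, array weights, fitting only the groups compared, a fold minimum (absolute log2 fold change of at least 1) and leaving out each array in turn. Centring each array on the 24 probe sets of the poly-A spike-ins, bacterial transcripts added to the RNA before labelling, was added after these probe sets were seen. This puts the median log2 fold change of all genes at 0.27 and 0.72 on days 3 and 6 of the wild type, at 0.31 and 0.18 on days 0 and 3 of upf1-1 over wild type, and at 0.23, 0.28 and 0.11 on days 0, 3 and 6 of upf3-1 over wild type. In the differences of change it puts the median at -0.12 and -0.25 for upf1-1 (days 3 and 6) and at -0.13 for upf3-1 (day 6). The changes reported here are relative to the deposited scale.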

Results

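Callus from hypocotyls was profiled on 0, 3 and 6 days of shoot-inducing medium in wild type Arabidopsis and in upf1-1 and upf3-1, with 3 arrays in each of the 9 groups. UPF1 and UPF3 are core factors of NMD, the pathway that degrades transcripts with premature or unusually placed stop codons. The series asks which transcripts the mutations affect while callus regenerates shoots. Values are log2 signals on a scale that runs from 2.04 to 13.48. Replicates of a group correlated with r between 0.993 and 0.998 across probe sets, and each of the 27 arrays was nearest to another array of its own genotype and day. The first principal component held 47.8% of the variance, the second 16.6% and the third 7.63%.

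UPF3 transcript was low in every upf3-1 array and raised in every upf1-1 array. Its log2 signal was 9.05 ± 0.047 (SD, n = 3), 9.08 ± 0.082 and 8.99 ± 0.015 in the wild type on days 0, 3 and 6. In the 9 upf3-1 arrays it was 6.03, 6.19 and 6.08 on day 0, 5.98, 6.38 and 5.87 on day 3, and 5.96, 5.96 and 5.70 on day 6. Against the wild type this is -2.95, -3.01 and -3.12 on the log2 scale (SE 0.095, limma adjusted p = 2.55e-16, 1.69e-16 and 7.26e-17). In upf1-1 UPF3 was higher than in the wild type by 0.59, 0.57 and 0.53. It is not known here whether the UPF3 probe set lies outside the part that the upf3-1 insertion removes from the transcript, so its signal is only a partial check of that label, and UPF1 was not analysed here.

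**Figure D1:**
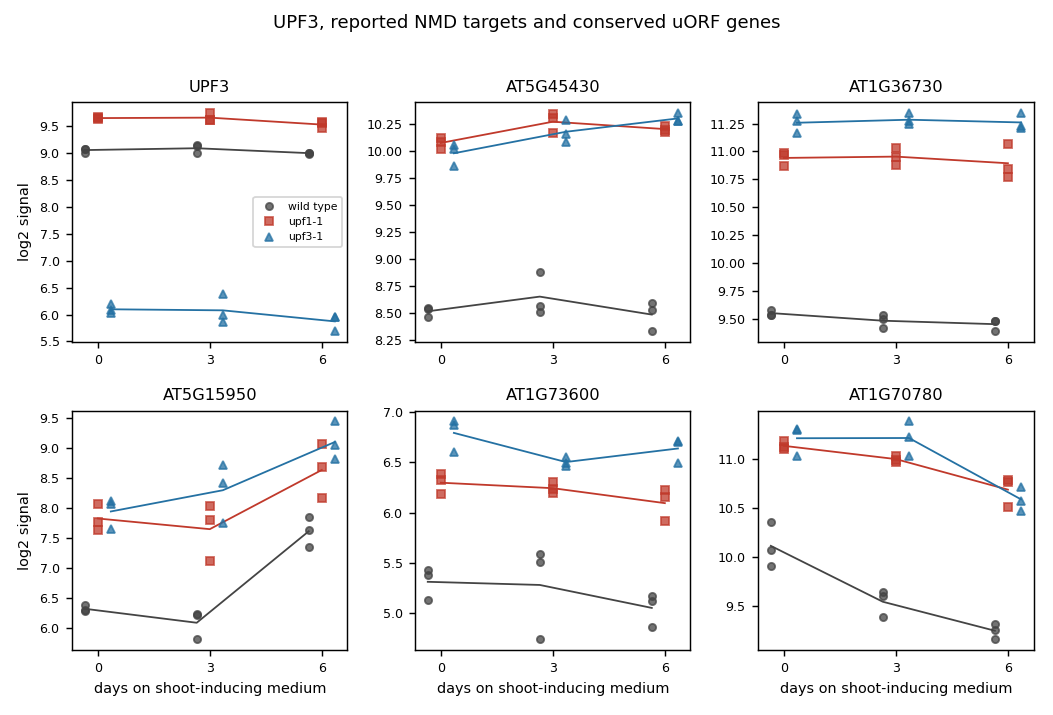
Log2 signal of UPF3, 2 reported NMD targets (AT5G45430 and AT1G36730) and 3 genes with a conserved uORF (AT5G15950, AT1G73600 and AT1G70780) against days on shoot-inducing medium, with 1 point per array (circles wild type, squares upf1-1, triangles upf3-1) and lines that join group means. UPF3 lies near 6 in upf3-1 and near 9 in the other genotypes, and the other 5 genes lie above the wild type in both mutants on each day.

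In the wild type, auxin-responsive genes were lower and both measured cytokinin-responsive genes higher after 3 days on shoot-inducing medium. No group stayed on callus-inducing medium, so an effect of the medium cannot be told from one of time. Of 8 measured early auxin genes, 7 fell, among them IAA20 (-2.58, SE 0.17), the lateral organ boundaries factor LBD16 (-2.37, SE 0.14) and the auxin-conjugating enzyme gene GH3.1 (-1.94, SE 0.21). Both measured type-A response regulators, which cytokinin induces, rose: ARR15 by 1.91 (SE 0.11) and RR16 by 2.67 (SE 0.21). The auxin biosynthesis gene YUC4 rose by 0.66 (SE 0.17). Among the largest changes were increases of the Bet v 1 family genes AT4G23670 (5.93, SE 0.37) and AT4G23680 (5.36, SE 0.15) and decreases of the GTPase gene AT4G09940 (-3.89, SE 0.13) and of PUCHI, an AP2/ERF factor of lateral root primordia (-3.20, SE 0.14).

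Root genes went both ways on day 3. The embryonic and root meristem factor BBM fell by 2.35 (SE 0.13) and the receptor kinase gene CR4 by 1.00 (SE 0.14), while the root hair expansin genes EXPA7 and EXPA18 rose by 2.36 (SE 0.17) and 1.63 (SE 0.18). Both measured cell cycle genes fell, the replication helicase gene PRL by 0.80 (SE 0.073) and the Aurora kinase gene AUR1 by 0.83 (SE 0.088). Of 10 uORF genes, 4 rose, led by the transcription factor gene bZIP44 (1.58, SE 0.09), and AT1G70780 fell by 0.57 (2 fell, adjusted over the list alone). Of the 6 photosynthesis genes only LHCB4.2 was called, at -0.69 (SE 0.14). No shoot meristem gene was called by limma (2 of 4 at an unadjusted p under 0.05); LAS stood at -0.29 and PHV at 0.24. None of the 3 stomatal lineage genes, of the starch and ABA genes APL3 and COR15A, or of SAG101 and PDF1.2 in the defence lists was called (0 at an unadjusted p under 0.05).

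In total 3793 of 13286 genes were called on day 3, 1717 higher and 2076 lower, and 499 of them changed at least 2-fold. Camera called the auxin list (median -0.98, adjusted p = 4.53e-07, and adjusted p = 0.0229 with an estimated correlation) and no other list. Adjusted over the list alone, CSA1 (0.42) and the flavonoid gene UGT78D2 (0.20) were higher and AT5G15710 (-0.18) lower. On the spike-in scale AT1G70780 (adjusted p = 0.167) and LHCB4.2 (0.129) were not called. Several smaller calls rested on single arrays. AT1G80000 of the exon junction list (-0.21) was not called without wild type day 0 replicate 2 (adjusted p = 0.0569), nor was the pigment gene DFR (-0.32; 0.0634). AT5G40920 (0.45) was lost without day 0 replicate 2 (0.117) and day 3 replicates 1 (0.05) and 3 (0.103), the anthocyanin gene AT4G14090 (0.39) without day 0 replicates 1 (0.0652) and 2 (0.0503) and day 3 replicate 2 (0.0676), and the reference gene AT5G46630 (0.17) without day 0 replicates 1 (0.0696) and 2 (0.0927) and day 3 replicates 2 (0.154) and 3 (0.0675).

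After 6 days the auxin, cytokinin and root changes stood at similar or larger values and photosynthesis genes had risen. All 8 early auxin genes were lower than on day 0, with LBD16 at -2.65 (SE 0.14), IAA20 at -2.44 and GH3.1 at -1.83, although GH3.3 (-0.72) and IAA29 (-0.61) turn to 0.02 and 0.12 when arrays are centred on the poly-A spike-ins. ARR15 was higher by 1.84 and RR16 by 2.72. BBM had fallen by 3.14 and CR4 by 1.74, and EXPA7 and EXPA18 had risen by 3.54 and 3.24 (SE 0.18 each). Of 6 photosynthesis genes 5 rose, among them PRK (1.41, SE 0.18), SBPASE (1.06, SE 0.23) and RCA (0.93, SE 0.13) of the Calvin cycle.

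Among the highest increases on day 6 were AT4G23670 (6.10, SE 0.37), AT1G27030 (4.71, SE 0.20) and the class III peroxidase genes AT1G30870 (4.50), AT3G49960 (4.43) and AT5G17820 (4.22). The largest decreases were AT4G09940 (-4.12) and the pectin-degrading polygalacturonase-like gene AT5G14650 (-4.05, SE 0.46). Of the uORF genes 5 rose and 2 fell, with AT5G15950, which codes for an enzyme of polyamine synthesis, at 1.29 (SE 0.24) and AT1G70780 at -0.87, while PMEAMT (-0.28) turns to 0.46 on the spike-in scale. PRL was lower by 0.89, and AUR1 was lower by 0.58, a value that turns to 0.16 on the spike-in scale. There PRL (adjusted p = 0.371) and AT1G70780 (0.453) were not called either. In the shoot meristem list LAS fell (-0.44, or 0.30 on the spike-in scale) and PHV rose (0.27), while CLV3, a marker of meristem stem cells, stood at 0.33 (SE 0.14) and was called only when adjusted over the list alone. CLV3 signals lay low on the scale and overlapped, at 3.11, 3.37 and 3.42 on day 0 and 3.39, 3.50 and 4.01 on day 6. They cannot be told from background here. The call of PHV was lost without wild type day 0 replicates 1 (adjusted p = 0.162) and 2 (0.118) and without day 6 replicates 1 (0.0703), 2 (0.155) and 3 (0.0566).

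On day 6, 4469 genes were called, 1914 higher and 2555 lower, and 636 changed at least 2-fold. The share that was higher was 42.8%, against 52.7% when arrays are centred on the reference genes and 98.1% when they are centred on the poly-A spike-ins; on day 3 these shares were 45.3%, 49.8% and 87.1%. Of the genes called on both days 1268 were higher and 1736 lower at both, and 4 changed in opposite directions. Camera called the auxin list (median -1.32, adjusted p = 1.62e-07, and adjusted p = 0.0185 with an estimated correlation). It called the photosynthesis list too (median 0.85, adjusted p = 0.00131), but not with an estimated correlation (adjusted p = 0.305 with an estimated correlation). The 3′ to 5′ signal difference of control transcripts, a measure of RNA integrity, moved by -0.11 from day 0 to day 6. The anthocyanin list had 0 called genes by limma (1 at an unadjusted p under 0.05), and the stomatal lineage genes, YUC4, SAG101 and PDF1.2 were not called either (0 at an unadjusted p under 0.05). The starch synthesis gene APL3 (-0.41) turns to 0.33 and the reference gene AT5G15710 (-0.21) to 0.52 on the spike-in scale, and AT1G80000 (-0.18) to 0.55. The call of APL3 was lost without 5 of the 6 arrays (highest adjusted p = 0.29, without wild type day 6 replicate 3), that of AT5G15710 without 4 (highest 0.165, without day 0 replicate 2), and that of AT1G80000 without 3 (highest 0.107, without day 0 replicate 2).

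**Figure D2:**
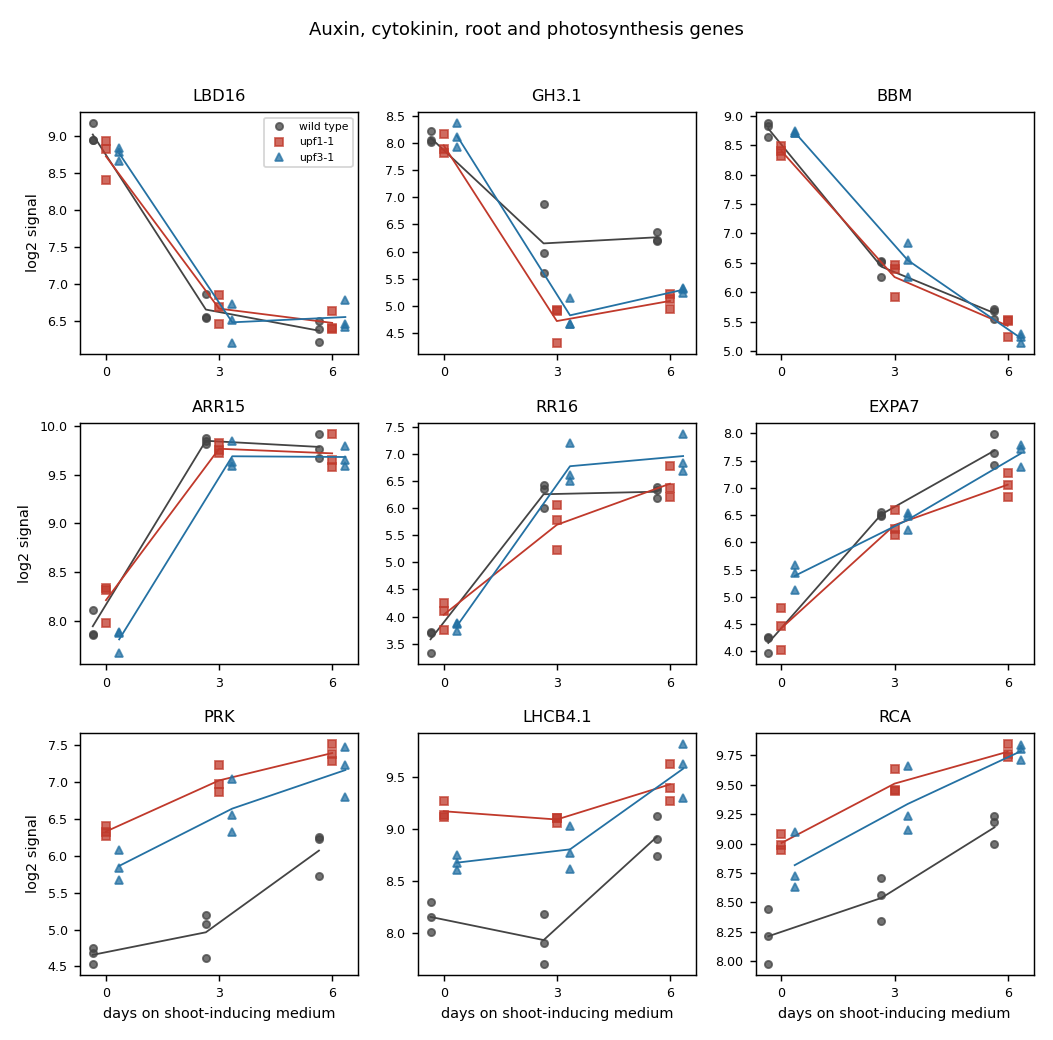
Log2 signal of auxin-responsive (LBD16, GH3.1), root (BBM, EXPA7), cytokinin-responsive (ARR15, RR16) and photosynthesis genes (PRK, LHCB4.1, RCA) against days on shoot-inducing medium, with 1 point per array (circles wild type, squares upf1-1, triangles upf3-1) and lines that join group means. Wild type LBD16 goes from 9.02 to 6.36 between days 0 and 6 and ARR15 from 7.94 to 9.79, and PRK lies above the wild type in both mutants on each day.

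The external controls moved with time as well. The poly-A spike-ins had a mean log2 signal of 6.25 ± 0.26 (SD, n = 3) on day 0, 5.98 ± 0.12 on day 3 and 5.52 ± 0.20 on day 6 in the wild type. The day 0 and day 6 means were 5.92 and 5.44 in upf1-1 and 6.00 and 5.38 in upf3-1. The hybridization controls, which are added after labelling, were at 8.95 ± 0.13 and 8.77 ± 0.03 on days 0 and 6 of the wild type. The mean of the 4 reference genes was 8.46 and 8.41.

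**Figure D3:**
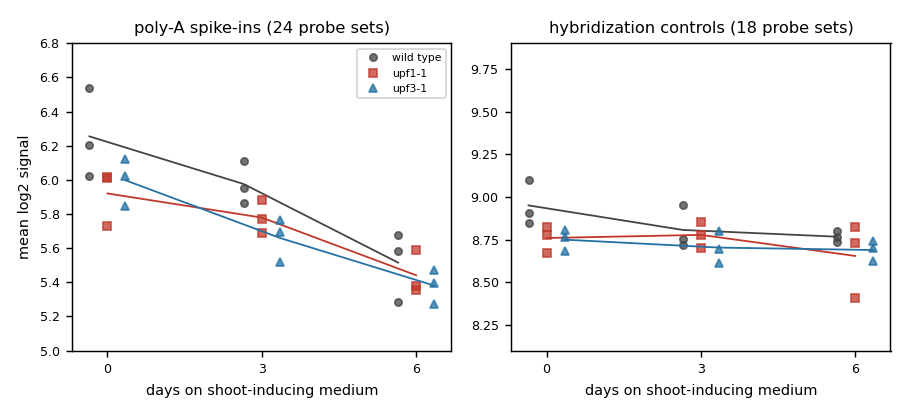
Mean log2 signal of the 24 poly-A spike-in probe sets (left) and the 18 hybridization control probe sets (right) against days on shoot-inducing medium, with 1 point per array (circles wild type, squares upf1-1, triangles upf3-1) and lines that join group means. In the wild type the spike-in mean goes from 6.25 to 5.52 between days 0 and 6.

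In upf1-1 reported NMD targets and uORF genes were higher than in the wild type on each day. All 6 measured NMD targets were called higher on day 0 and 5 on days 3 and 6 (6 and 5, adjusted over the list alone). The kinase gene AT5G45430 was higher by 1.56, 1.62 and 1.71 on days 0, 3 and 6 (SE 0.086), and AT1G36730, which codes for a translation initiation factor eIF5, by 1.39, 1.47 and 1.45 (SE 0.072). AT5G40920, annotated as a pseudogene of a resistance gene, was called on day 0 only (0.47), and not without wild type day 0 replicate 2 (adjusted p = 0.143), upf1-1 day 0 replicate 1 (0.0685) or replicate 3 (0.0872). Of the 10 uORF genes 6, 5 and 5 were higher on the 3 days (8, 6 and 5, adjusted over the list alone) and 0 lower. They include AT5G15950 (1.50, 1.56 and 1.02, SE 0.24), AT1G70780 (1.02, 1.46 and 1.44, SE 0.11), AT5G09460 (1.21, 1.07 and 1.19, SE 0.09) and AT1G73600, a methyltransferase gene of phospholipid synthesis (0.99, 0.96 and 1.04, SE 0.15). Camera called the NMD target list on days 0, 3 and 6 (medians 0.61, 0.63 and 0.67, adjusted p = 1.59e-09, 2.49e-08 and 8.73e-09) and the uORF list (medians 0.58, 0.51 and 0.56, adjusted p = 5.94e-08, 2.19e-05 and 1.34e-05). These calls held with an estimated correlation. Of the 4 NMD and exon junction factors UPF3 and AT1G80000 were higher on each day (0.19, 0.32 and 0.34 for AT1G80000). The day 0 call of AT1G80000 was lost without wild type day 0 replicate 1 (0.185) and without upf1-1 day 0 replicates 1 (0.0548), 2 (0.108) and 3 (0.0697).

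Photosynthesis genes were higher in upf1-1 too. All 6 were called on days 0 and 3 and 5 on day 6 (6 on each day, adjusted over the list alone), with PRK at 1.67, 2.06 and 1.32 (SE 0.18), SBPASE at 1.27 and 1.17 on days 0 and 3, and LHCB4.1, of the antenna of photosystem II, at 1.01, 1.15 and 0.50 (SE 0.13). Camera called the list on days 0, 3 and 6 (medians 0.91, 1.06 and 0.59, adjusted p = 5.77e-08, 3.49e-08 and 0.000108). With an estimated correlation it was called on days 0 and 3 and not on day 6 (adjusted p = 0.0339, 0.0311 and 0.172 with an estimated correlation). The 3′ to 5′ signal difference of control transcripts, a measure of RNA integrity, differed from the wild type by -0.08, 0.02 and 0.07 on these days, beside a pooled SD of 0.074 (0.0432 without upf1-1 day 6). No stomatal lineage gene, a marker of green shoot epidermis, was called (0 at an unadjusted p under 0.05).

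Among hormone and tissue genes, GH3.1 and YUC4 were lower in upf1-1 on the later days. GH3.1 stood at -0.14 on day 0, -1.43 on day 3 and -1.17 on day 6 (SE 0.21), and YUC4 at -0.41, -1.45 and -0.86 (SE 0.17). The values of days 3 and 6 were called. YUC4, the only measured member of its list, had on day 0 just an unadjusted p under 0.05 by limma. LBD29 was higher on day 0 (0.69) and IAA20 on day 3 (0.66). CR4 was lower on day 0 (-0.55) and day 3 (-0.50), the latter not without wild type day 3 replicate 2 (adjusted p = 0.101) or upf1-1 day 3 replicate 3 (0.0922), and PRL was lower on day 0 (-0.39). CSA1, an NLR immune receptor gene, was lower on day 0 (-0.70, SE 0.16). On the spike-in scale CSA1 (adjusted p = 0.118) and, on day 0, CR4 (0.288) and PRL (0.762) were not called. Neither cytokinin gene was called over all genes on any day by limma (2, 1 and 0 at an unadjusted p under 0.05), and on day 0 both were higher when adjusted over the list alone (0.27 for ARR15 and 0.45 for RR16). Adjusted over the list alone, RR16 was lower on day 3 (-0.56), LAS on day 0 (-0.35), and AT4G14090 (-0.36) and PRL (-0.19) on day 6, while DFR was higher on day 3 (0.23). No shoot meristem, anthocyanin, jasmonate, salicylic acid or reference gene of the lists was called on any day. At an unadjusted p under 0.05 these were 1, 1 and 0 of 4 shoot genes, 0, 1 and 1 of 3 anthocyanin genes and 1, 0 and 0 of 4 reference genes on days 0, 3 and 6, and 0 of SAG101 and PDF1.2.

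Several smaller list calls in upf1-1 did not hold without single arrays. BBM on day 0 (-0.38) was lost without 5 of 6 arrays (highest adjusted p = 0.152, without wild type day 0 replicate 2). PRL on day 3 (-0.23) was lost without upf1-1 day 3 replicate 3 (0.153) and wild type day 3 replicates 2 (0.144) and 3 (0.0509). EXPA7 on day 6 (-0.63) was lost without wild type replicate 3 (0.102) and upf1-1 replicate 1 (0.0733), GH3.3 (-0.49) without upf1-1 replicate 2 (0.123) and wild type replicate 1 (0.109), and WES1 (-0.39) without 4 arrays (highest 0.258, without upf1-1 day 6 replicate 2). APL3 was higher on days 0 (0.48) and 6 (0.55) and at 0.43 on day 3 (called there when adjusted over the list alone). Its day 0 call was lost without 5 arrays (highest 0.107, without upf1-1 day 0 replicate 1) and its day 6 call without wild type replicate 3 (0.105) and upf1-1 replicate 3 (0.0542).

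The genes with the largest differences on day 0 were the glycosyltransferase gene AT4G15260 (2.24, SE 0.11), the glucosidase gene BGLU33 (2.19, SE 0.39) and AT3G53400 (2.09, SE 0.08) on the higher side and the subtilase gene SBT1.3 (-1.87, SE 0.22) and the bHLH gene AT2G43140 (-1.86, SE 0.17) on the lower. On day 3 the GDSL lipase gene AT1G54020 (2.72, SE 0.51) and BGLU33 (2.62) were highest, and AT3G60420 (-4.89, SE 0.89), the AAA-ATPase gene AT3G28510 (-4.20, SE 0.76) and AT2G25510 (-3.97, SE 0.43) were lowest. AT1G54020, AT3G60420 and AT3G28510 were uneven among wild type arrays of day 3, with 5.96 ± 1.4 (SD, n = 3), 8.99 ± 1.5 and 6.91 ± 1.3, as was BGLU33 on day 0 (5.45 ± 1.0). On day 6 the receptor kinase gene AT5G59670 (2.72, SE 0.21) and the linker histone gene HIS1-3 (2.37, SE 0.39; wild type 5.80 ± 1.1) were highest, and AT1G09310 (-3.50, SE 0.31) and the isocitrate lyase gene ICL (-2.70, SE 0.28) lowest.

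Over all genes 2272, 2282 and 2351 were called in upf1-1 on days 0, 3 and 6, of which 1231, 1310 and 1389 were higher, and 159, 215 and 164 differed at least 2-fold. The share that was higher was 54.2%, 57.4% and 59.1%. It was 70.7%, 64.3% and 70.5% with arrays centred on the reference genes and 98.3%, 90.3% and 82.7% with arrays centred on the poly-A spike-ins. On the latter scale 995 genes were called on day 6, and 1498 when only the groups compared were fitted.

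In upf3-1 the same lists stood out. Of the 6 NMD targets 5 were higher on each day and UPF3 itself was lower. AT1G36730 was higher by 1.71, 1.81 and 1.81 on days 0, 3 and 6 (SE 0.072), AT5G45430 by 1.46, 1.52 and 1.81 (SE 0.086) and AT5G40920 by 0.96, 0.61 and 0.98 (SE 0.14). Of the 10 uORF genes 6, 7 and 6 were higher (7, 7 and 6, adjusted over the list alone) and 0 lower, with AT5G15950 at 1.62 and 1.48 on days 0 and 6 (SE 0.24), AT1G73600 at 1.48, 1.22 and 1.59 (SE 0.15), AT1G70780 at 1.10, 1.67 and 1.34 and the polyamine synthesis gene SAMDC at 0.60, 0.65 and 0.75. Camera called the NMD target list (medians 0.71, 0.65 and 0.72, adjusted p = 0.0004, 0.000844 and 0.000507) and the uORF list (medians 0.55, 0.69 and 0.54, adjusted p = 7.58e-08, 4.11e-06 and 6.02e-07), and these calls held with an estimated correlation. It also called the list of NMD and exon junction factors on day 0 (median -0.23, adjusted p = 0.0488), but not with an estimated correlation (adjusted p = 0.147 with an estimated correlation) nor without wild type day 0 replicates 2 (0.073) or 3 (0.0923) or upf3-1 day 0 replicate 2 (0.0803), and its median turns to 0.03 on the spike-in scale, which moves all genes alike (adjusted p = 0.00015 there). UPF3, the gene mutated in upf3-1, is among the 4 measured genes of this list. The call is therefore not independent of the mutation and does not show by itself that other NMD factors were lower.

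Photosynthesis genes were higher in upf3-1 as well, with 5, 6 and 5 of 6 called (6 on each day, adjusted over the list alone). PRK stood at 1.68 and 1.09 on days 3 and 6 (SE 0.18), RCA at 0.60, 0.80 and 0.65 (SE 0.13) and LHCB4.2 at 0.47, 0.80 and 0.88 (SE 0.14) on days 0, 3 and 6. LHCB4.1 on day 0 (0.52) was not called without wild type day 0 replicate 1 (adjusted p = 0.0528). The list was called on days 0, 3 and 6 at the preset correlation (medians 0.56, 0.80 and 0.65, adjusted p = 0.000141, 4.11e-06 and 6.84e-05) and on no day otherwise (adjusted p = 0.179, 0.0889 and 0.163 with an estimated correlation). The 3′ to 5′ signal difference of control transcripts differed from the wild type by -0.11, -0.03 and 0.05, beside a pooled SD of 0.074 (0.0432 without upf1-1 day 6). No stomatal lineage gene was called over all genes by limma (0, 0 and 1 of 3 at an unadjusted p under 0.05), and MUTE at -0.31 on day 6 was called lower when adjusted over the list alone.

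GH3.1 was lower in upf3-1 on day 3 (-1.32) and day 6 (-0.96) and at 0.04 on day 0 (SE 0.21), and YUC4 was lower on days 3 (-1.17) and 6 (-0.67). EXPA7 was higher on day 0 (1.23, SE 0.17; EXPA18 at 0.48 was called too when adjusted over the list alone), and CR4 was lower on day 3 (-0.69). PRL was lower on day 3 (-0.32) and day 6 (-0.39). On the spike-in scale CR4 (adjusted p = 0.103) and PRL (0.98 and 0.481) were not called. Adjusted over the list alone, IAA29 (-0.47) and LAS (-0.33) were lower and RR16 (0.52) higher on day 3, and COR15A was lower on day 0 (-0.24). PDF1.2, the only measured member of its list, was lower on day 6 (-0.27) at an unadjusted p under 0.05 by limma. Other list calls were lost without single arrays: PHV (-0.30 on day 3, 0.01 on the spike-in scale, and -0.37 on day 6) without 4 arrays on day 3 (highest adjusted p = 0.216, without upf3-1 replicate 1) and on day 6 without upf3-1 replicate 2 (0.0545) and wild type replicate 2 (0.0565). DFR on day 0 (-0.31) was lost without wild type replicate 2 (0.105), and AT4G14090 on day 3 (-0.39) without 5 arrays (highest 0.097, without upf3-1 replicate 1). The defensin gene PDF1.2 on day 3 (-0.33) and GH3.3 (-0.38) were lost without 5 arrays each (highest 0.23, without upf3-1 replicate 2, and 0.204, without wild type replicate 3). BBM (-0.43) and AUR1 (-0.28) on day 6 were lost without 4 arrays each (highest 0.0857, without upf3-1 replicate 1, and 0.12, without upf3-1 replicate 3), and RR16 (0.66) without 3 (highest 0.184, without upf3-1 replicate 1). APL3 was higher on each day (0.44, 0.56 and 0.57). Its day 0 call was lost without 5 arrays (highest 0.14, without upf3-1 replicate 3), that of day 3 without wild type replicate 2 (0.0801) and that of day 6 without wild type replicate 3 (0.0852). The salicylic acid list (SAG101) and the reference genes had no call on any day (0, 0 and 1 of 4 reference genes and 0 of SAG101 at an unadjusted p under 0.05).

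The genes furthest above the wild type in upf3-1 were AT4G15260 (2.89, SE 0.11) on day 0 and the orphan gene QQS, which affects leaf starch, on days 3 (3.85, SE 0.28) and 6 (3.28). The annotated pseudogenes AT3G21020 (2.82, 2.73 and 3.20, SE 0.22) and AT2G13970 (2.47 and 2.55 on days 0 and 6, SE 0.09) were among the highest, as were AT2G16005 (3.70, SE 0.61) and the PR-1-like gene AT1G50060 (3.68, SE 0.37) on day 3. The upf3-1 arrays of day 3 were uneven at AT2G16005 (9.62 ± 1.3, SD, n = 3) and AT1G50060 (6.55 ± 1.1). Besides UPF3, genes far below the wild type were the polygalacturonase-like gene AT1G60590 on day 0 (-1.75, SE 0.24), AT2G25510 on day 3 (-2.89, SE 0.43) and ICL on day 6 (-2.30, SE 0.28). AT3G60420 on day 3 (-3.02, SE 0.89) was lower still but was not called without wild type replicate 3 (adjusted p = 0.107) or upf3-1 replicates 1 (0.0788) and 2 (0.0608).

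Over all genes 2035, 2994 and 2443 were called in upf3-1 on days 0, 3 and 6, of which 1118, 1453 and 1305 were higher, and 169, 300 and 199 differed at least 2-fold. The share that was higher was 54.9%, 48.5% and 53.4%. It was 70.2%, 72.2% and 79.7% with arrays centred on the reference genes and 96.8%, 96.8% and 88.6% with arrays centred on the poly-A spike-ins, where 1162 genes were called on day 6. When only the groups compared were fitted, 1242 genes were called on day 0.

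Both mutants raised many of the same genes. On all 3 days 551 genes were higher in both and 88 lower in both, and 43 of the 551 and 0 of the 88 differed at least 2-fold in each comparison. The largest mean changes were of AT4G15260 (2.24, 2.01 and 1.97 in upf1-1 and 2.89, 2.63 and 2.78 in upf3-1 on days 0, 3 and 6), AT5G59670 (1.89, 2.37 and 2.72, and 2.22 and 2.40 on days 0 and 3), AT3G53400, AT2G13970, AT3G21020 and CPUORF47, whose name marks a conserved uORF. The count of genes lower in both was 55 without wild type day 0 replicate 1 and 48 without replicate 2, and it was 33 with arrays centred on the reference genes and 5 with arrays centred on the poly-A spike-ins.

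Log2 fold changes of the mutants correlated across genes with r = 0.72, 0.68 and 0.79 on days 0, 3 and 6 (jackknife SE 0.047, 0.12 and 0.059 over arrays), where genes are not independent replicates. Simulated unchanged mutants that share the wild type arrays gave medians of r = 0.50, 0.50 and 0.50, and at most 0.53 in 100 draws. The covariances were 0.0581, 0.0738 and 0.0714 against simulated values of 0.00765, 0.00768 and 0.0077, a difference of 0.0504, 0.0661 and 0.0637. Genes higher in both numbered 793, 896 and 962, where independent lists give 104, 143 and 136, and genes lower in both 400, 558 and 509, where independent lists give 71.8, 113 and 82.4. Simulated medians were 0 for both, but the simulated mutants had no changed genes, so this gives no baseline for these overlaps. Part of the excess over independent lists may come from the shared wild type arrays, since 3 arrays are too few for each mutant to have its own. Genes that moved in opposite directions numbered 10, 11 and 5. The count lower in both on day 0 was 246 and 216 without wild type day 0 replicates 1 and 2, and that on day 6 was 318 without wild type day 6 replicate 1. With arrays centred on the reference genes 198, 320 and 238 genes were lower in both, and with arrays centred on the spike-ins 18, 54 and 65. On the latter scale 1367 were higher in both on day 0.

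**Figure D4:**
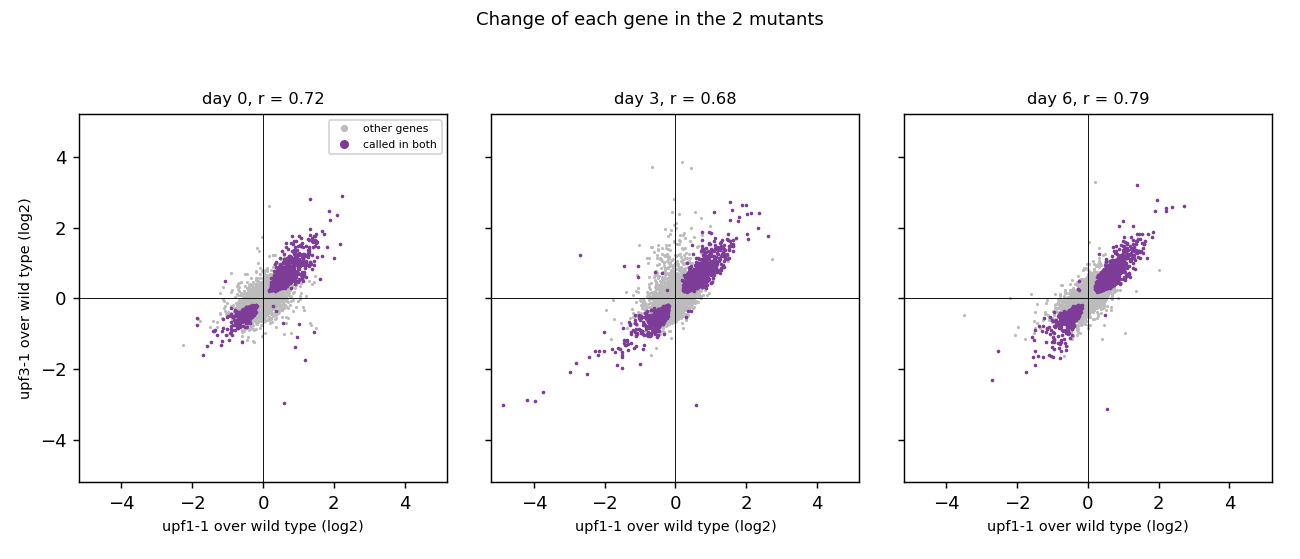
Log2 fold change of each of 13286 genes in upf3-1 over wild type against that in upf1-1 over wild type on days 0, 3 and 6, with genes called in both mutants in purple and Pearson's r above each panel. Most genes called in both lie at the upper right or lower left, and UPF3 lies alone near 0.6 on the horizontal and -3 on the vertical axis.

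Few genes were called as changing differently over time in the mutants than in the wild type. At an unadjusted p under 0.05 by limma there were 1241 and 1291 to days 3 and 6 in upf1-1. In upf3-1 there were 1814 and 1538. The median SE of these contrasts was 0.142, beside 0.1 for upf1-1 over wild type on day 0, so smaller differences can be missed. The change of the auxin conjugation family gene AT1G23160 was more positive in upf1-1 than in the wild type to days 3 and 6 (by 2.07 each, SE 0.36). Its mean signal went from 5.99 to 7.32 and 8.36 in upf1-1 and from 7.69 to 6.95 and 7.99 in the wild type. AT2G25510 rose by day 3 in the wild type and went from 4.08 to 4.03 in upf1-1 (-3.39, SE 0.61). AT1G09310 went from 7.41 to 7.52 by day 6 in the wild type and from 6.53 to 4.03 in upf1-1 (-2.61, SE 0.43). By day 3 the oxidase-like gene AT5G44380 went from 8.01 to 6.12 in the wild type and from 7.03 to 7.59 in upf3-1 (2.45, SE 0.43). The chitinase gene AT2G43610 went from 8.20 to 7.78 and from 7.30 to 9.20 (2.32, SE 0.35), and the root hair gene EXPA7 went from 4.15 to 6.52 and from 5.38 to 6.42 (-1.33, SE 0.25). By day 6 the chitinase gene ChiC went from 5.77 to 5.74 in the wild type and from 4.79 to 6.71 in upf3-1 (1.96, SE 0.36). ICL went from 5.54 to 7.15 and from 5.66 to 4.84 (-2.42, SE 0.39). When only the groups compared were fitted, AT1G23160 to day 3 in upf1-1 (adjusted p = 0.0739), AT5G44380 (0.0572) and ChiC (0.0506) were not called.

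These differences of change were called for 32 genes (13 higher, 19 lower) to day 3 and 60 (31 and 29) to day 6 in upf1-1, and for 88 (56 and 32) and 48 (20 and 28) in upf3-1. The share of higher calls moved from 63.6% to 79.3% (upf3-1, day 3) and from 41.7% to 58.1% (upf3-1, day 6) with arrays centred on the reference genes. With arrays centred on the spike-ins it was 6.9% and 9.62% in upf1-1 on days 3 and 6, beside 40.6% and 51.7%, and 80.4% and 19.2% in upf3-1. With array weights the counts to day 3 were 56 and 188 in upf1-1 and upf3-1, and 20 and 44 when only the groups compared were fitted. Reference gene centring gave 21 to day 3 in upf1-1, and spike-in centring 56 and 26 to days 3 and 6 in upf3-1. Single arrays moved the counts too. To day 3 in upf1-1 the count was 17 without wild type day 0 replicate 2, 14 and 21 without upf1-1 day 0 replicates 1 and 2, and 19 and 17 without upf1-1 day 3 replicates 1 and 2. To day 6 it was 30 without wild type day 6 replicate 3, 30 without upf1-1 day 0 replicate 1 and 34 without upf1-1 day 6 replicate 1. In upf3-1 the count to day 3 was 48 without wild type day 0 replicate 1, 50 without wild type day 3 replicate 3, and 48, 316 and 57 without upf3-1 day 3 replicates 1, 2 and 3. That to day 6 was 84 without wild type day 0 replicate 2, 31 without wild type day 6 replicate 1, 26 and 98 without upf3-1 day 0 replicates 2 and 3, and 31 and 27 without upf3-1 day 6 replicates 1 and 3.

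Of the lists tested for such a difference, only the early auxin list of upf3-1 on day 3 (GH3.1) and the root list of upf3-1 on days 3 and 6 (EXPA7) held called genes. The call of GH3.1 (-1.36) was lost without 6 of 12 arrays (highest adjusted p = 0.0969, without upf3-1 day 3 replicate 1), and that of EXPA7 to day 6 (-1.28) without upf3-1 day 0 replicate 2 (0.0657) and day 6 replicate 1 (0.0527). Adjusted over the list alone, GH3.1 (-1.29), LBD29 (-0.71), ARR15 (-0.35) and RR16 (-1.02) were lower and DFR higher (0.37) to day 3 in upf1-1, and GH3.1 (-1.03) and EXPA7 (-0.90) were lower to day 6. YUC4, the only measured member of its list, was lower to day 3 in upf1-1 (-1.03) and upf3-1 (-0.92) at an unadjusted p under 0.05 by limma. In upf3-1 adjustment over the list alone gave PRL (-0.24) and AUR1 (-0.30) as lower and AT1G70780 (0.57) and DFR (0.46) as higher to day 3. To day 6 it gave GH3.1, PRL (-0.31) and AUR1 (-0.40) as lower and IAA20 (0.62), LBD29 (0.55) and AT5G45430 (0.35) as higher. Camera called the photosynthesis list in upf1-1 to day 6 (median -0.31, adjusted p = 0.0162; adjusted p = 0.513 with an estimated correlation), but not without wild type day 0 replicate 1 (0.145) or wild type day 6 replicates 2 (0.0693) and 3 (0.134). It called the root list in upf3-1 to day 6 (median -0.38, adjusted p = 0.0208; adjusted p = 0.168 with an estimated correlation), but not without wild type day 0 replicate 3 (0.0526), wild type day 6 replicate 3 (0.0619), upf3-1 day 0 replicate 3 (0.0957) or upf3-1 day 6 replicate 1 (0.0502).

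The mutants differed from each other at fewer genes than either did from the wild type. QQS was higher in upf3-1 than in upf1-1 by 2.45, 3.67 and 3.08 on days 0, 3 and 6 (SE 0.28), AT1G09310 by 3.93 and 3.03 on days 3 and 6 (SE 0.31) and AT2G16005 by 4.36 on day 3 (SE 0.61). AT2G16005 was uneven in both mutants on day 3, with 5.26 ± 1.5 (SD, n = 3) in upf1-1 and 9.62 ± 1.3 in upf3-1. AT1G60590 and AT1G10640, both polygalacturonase-like, were lower on day 0 (-2.94 and -2.40). Among NMD targets AT1G36730 was higher in upf3-1 by 0.32, 0.33 and 0.37 (SE 0.072); the day 0 call was lost without upf1-1 day 0 replicate 2 (adjusted p = 0.0733) and upf3-1 day 0 replicate 3 (0.0546). None of these 3 calls of AT1G36730 held when only the groups compared were fitted (adjusted p = 0.0745, 0.0519 and 0.145) or on the spike-in scale (0.854, 0.122 and 0.421). The response regulator gene RR16 was higher in upf3-1 on day 3 (1.08, SE 0.21; adjusted p = 0.0534 when only the groups compared were fitted), and on day 0 the auxin gene LBD29 was lower (-0.93, SE 0.15) and the NLR gene CSA1 higher (0.97, SE 0.16).

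In total 510 genes were called between the mutants on day 0 (272 higher in upf3-1, 238 lower), 1053 on day 3 (582 and 471) and 298 on day 6 (167 and 131). The count of day 0 was 244, 314 and 304 without upf1-1 replicates 1, 2 and 3 and 267 without upf3-1 replicate 2. That of day 3 was 523 without upf1-1 replicate 2 and 370 and 560 without upf3-1 replicates 1 and 3, and that of day 6 was 147 without upf1-1 replicate 2 and 133 and 168 without upf3-1 replicates 2 and 3. Array weights gave 2696 genes on day 3, fits of only the groups compared 409 and 97 on days 3 and 6, and spike-in centring 151, 430 and 49. Shares of higher calls were 53.3%, 55.3% and 56%, against 46.9%, 81.6% and 81.2% with arrays centred on the reference genes and 27.8%, 94.9% and 73.5% on the spike-in scale. Camera called the list of NMD and exon junction factors on each day (medians -0.10, -0.15 and -0.18, adjusted p = 0.000261, 0.00327 and 9.31e-05), also with an estimated correlation but on day 3 not when only the groups compared were fitted (adjusted p = 0.0963), and in it only UPF3 was called. On day 0 it called the photosynthesis list (median -0.40, adjusted p = 0.000927; adjusted p = 0.287 with an estimated correlation), with 2 of 6 genes lower (3 adjusted over the list alone). These 2, LHCB4.1 (-0.49) and PORB (-0.49), were lost without 6 and 5 of the 6 arrays (highest adjusted p = 0.157, without upf1-1 day 0 replicate 1, and 0.123, without upf1-1 day 0 replicate 3) and on the spike-in scale (0.232 and 0.234). It also called the root list (median 0.33, adjusted p = 0.00494; adjusted p = 0.0889 with an estimated correlation), with EXPA7 higher by 0.96 (SE 0.17).

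Some differences between the mutants were called only when adjusted over the list alone. On day 0 AT5G40920 (0.49), AT1G73600 (0.50), PMEAMT (0.29), BBM (0.32) and AUR1 (0.21) were higher in upf3-1 on this count. AT2G45670 (-0.25), bZIP44 (-0.24), AT3G25570 (-0.34), PRK (-0.47) and COR15A (-0.30) were lower. On day 3 UGT78D2 was higher (0.23) and PHV lower (-0.30). On day 6 AT1G73600 (0.54), CSA1 (0.36), RR16 (0.51), EXPA7 (0.57), EXPA18 (0.46) and AT4G14090 (0.35) were higher. SAG101 (0.49), the only measured member of its list, was higher at an unadjusted p under 0.05 by limma. AT2G45670 (-0.31), AT3G63340 (-0.21), PRL (-0.20), AUR1 (-0.20), MUTE (-0.42) and the reference gene AT2G28390 (-0.22) were lower.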

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

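The tests of the poly-A spike-ins and the tests of technical causes for the photosynthesis genes were chosen only after those results had been seen. A fold change in one genotype or on one day that differed from another by a test of the difference itself is listed here, as is a signal in control probe sets that no comparison of genes uses. Values are log2 unless they are counts, and the calls are those of limma over all genes.

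The change over time differed between upf1-1 and the wild type at 32 genes to day 3 and at 60 to day 6. The genes named to day 3 are AT1G23160 (2.07), HPR (1.04) of photorespiration, the peroxidase gene AT5G64110 (1.02), AT2G25510 (-3.39), AT1G10640 (-2.23) and the glutaredoxin gene AT4G15700 (-1.67). To day 6 they are AT1G23160 (2.07), AT1G25230 (1.60), AT2G43140 (1.49), AT1G09310 (-2.61), AT3G29970 (-2.40) and AT1G10640 (-2.29).

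Between upf3-1 and the wild type the change differed at 88 genes to day 3 and at 48 to day 6. To day 3 these include AT5G44380 (2.45), AT1G50060 (2.33), AT2G43610 (2.32), AT4G15700 (-1.68), GH3.1 (-1.36), BAT1 (-1.35) and EXPA7 (-1.33). To day 6 they include the peroxidase gene AT2G18980 (2.09), ChiC (1.96), AT1G23160 (1.71), ICL (-2.42), the lipase gene AT5G45670 (-1.63), the small heat shock protein gene AT5G51440 (-1.62) and EXPA7 (-1.28). AT1G23160 to days 3 and 6 in upf1-1, AT4G15700 in both mutants and EXPA7 to day 3 stayed called whichever array was left out. The calls of AT1G23160 and AT4G15700 to day 3 in upf1-1 were lost when only the groups compared were fitted. Calls lost without 8 or more of the 12 arrays include AT5G64110, AT3G29970, AT1G50060, BAT1 and AT2G18980. They also include AT1G10640 to day 3 in upf1-1 and AT1G23160 to day 6 in upf3-1. When the residuals of a fit without these differences were drawn over the 12 arrays, only the real order of 100 reached its count. The highest other counts were 2 and 1 for upf1-1 and 40 and 12 for upf3-1 on days 3 and 6. Among these samples chance can thus be excluded as the source of each whole count. It cannot be excluded for a part of the calls or for single genes.

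On day 0 upf3-1 and upf1-1 differed at 510 genes, with QQS at 2.45, the rhodanese-like gene AT2G17850 at 1.61, AT4G39675 at 1.58, UPF3 at -3.55, AT1G60590 at -2.94 and AT1G10640 at -2.40. List members were AT1G36730 (0.32), CSA1 (0.97), LBD29 (-0.93), ARR15 (-0.40), EXPA7 (0.96), LHCB4.1 (-0.49), PORB (-0.49) and PRL (0.31). On day 3 they differed at 1053 genes, with AT2G16005 at 4.36 (arrays uneven in both mutants), AT1G09310 at 3.93, QQS at 3.67, UPF3 at -3.58, AT2G07722 at -1.06 and the cysteine protease gene AT1G29090 at -0.98, and with AT1G36730 (0.33), CSA1 (0.62), IAA20 (-0.63) and RR16 (1.08) in the lists. On day 6 they differed at 298 genes, with QQS at 3.08, AT1G09310 at 3.03, AT3G21020 at 1.80, UPF3 at -3.65, AT1G54020 at -2.04 and the carboxypeptidase gene AT5G22860 at -1.54, and with AT5G40920 (0.70), AT1G36730 (0.37) and PHV (-0.40) in the lists. Many of the list calls do not hold. On day 0 LHCB4.1 was lost without each of the 6 arrays, PORB without 5, ARR15 without 4, PRL without 3 and AT1G36730 without 2, and all 5 on the spike-in scale. On day 3 CSA1 was lost without 5 arrays and IAA20 without 3. On day 6 PHV was lost without each of the 6 and with centring on the reference genes (adjusted p = 0.114), and AT5G40920 without upf1-1 day 6 replicate 2 (0.0653) and when only the groups compared were fitted (0.063). Of the other genes AT2G17850 and AT4G39675 were lost without 4 arrays each, AT1G54020 without 5 and AT1G29090 without 1. The probe set of AT2G07722 may also bind transcripts of other genes by its name.

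For comparisons of 3 arrays with 3 others, 1 of 10 splits, the real one, reached the real count in each case, and 10 splits are too few to exclude chance. The highest count of any other split was 1 on both days of the wild type, 0, 0 and 1 for upf1-1, 2, 2 and 0 for upf3-1, and 0, 1 and 0 between the mutants on days 0, 3 and 6.

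The first pattern weighed is the larger difference between the mutants on day 3 (1053 genes, beside 510 on day 0). Without upf3-1 day 3 replicate 1 the count was 370, which lies under the limit set beforehand, the day 0 count of 6 arrays. That limit sets 5 arrays against 6, and a count can fall by the loss of an array alone. On day 0 counts from 5 arrays ran from 244 to 529, so the limit cannot decide. Without upf3-1 day 3 replicate 2 the count was 1429, and with array weights 2696. Whether a single array made the difference larger cannot be told with 3 arrays per group.

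Poly-A spike-in signals, which lie outside the genes compared, went down from day 0 to day 6 (medians of 24 probe sets -0.736 in the wild type, -0.509 in upf1-1 and -0.608 in upf3-1). All 9 day 6 arrays lay below every day 0 array of their genotype (mean change -0.612, exact permutation p = 0.00025, two-sided, the smallest that 8000 arrangements allow). A shift of all controls alike by the authors' normalization can be excluded as the whole cause, since hybridization controls moved by at most 24.8% as much. These controls are brighter (8.951 beside 6.255 in the wild type on day 0). An effect of normalization on weaker signals alone therefore cannot be excluded. Less spike-in RNA per amount of total RNA on later days, or more poly-A RNA in the cells, would each give the change of -0.612, and the data cannot tell them apart without a record of the amounts. If the latter holds, counts of genes that fell over time are too high.

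Of 6 photosynthesis genes 5 or 6 were called higher in each mutant on each day, but the list kept its call only in upf1-1 on days 0 and 3 and lost it elsewhere (adjusted p = 0.172 in upf1-1 on day 6 and 0.179, 0.0889 and 0.163 in upf3-1 with an estimated correlation). Centred on the reference genes the list median kept at least 101.6% of its value in the 6 comparisons. A shift shared with these 4 genes therefore does not make the difference. They are themselves normalized values, so an effect of the authors' normalization cannot be excluded in this way. RNA quality, measured by the 3′ to 5′ signal difference, was tested as a covariate. All 6 genes were then called in each of the 5 comparisons other than upf3-1 on day 0. Without upf1-1 day 6, the most uneven group, they were called in each of the 4 left. The covariate took the genes called in upf1-1 from 2272 to 2142 on day 0 and from 2282 to 2374 on day 3. These values argue against this measure as the whole cause in the 5 comparisons. As 105 genes followed it with all arrays and 0 without upf1-1 day 6, they cannot exclude RNA quality in other respects. RNA quality stays open as a cause in upf3-1 on day 0, where 3 genes were still called with the covariate. Without upf1-1 day 6 it was 2, with a list median of 0.341 beside 0.562 in the fit without the covariate. With all arrays LHCB4.1 went from 0.52 (SE 0.13) to 0.42 (SE 0.14) and LHCB4.2 from 0.47 (SE 0.14) to 0.45 (SE 0.16). Their calls ended as folds shrank and SEs grew (limma adjusted p = 0.0502 and 0.069). Cells of another type, such as those of leaves with stomata, cannot be told apart from a response within callus cells: no stomatal lineage gene was called higher (0 of 18 tests), but SPCH, MUTE and FMA had mean signals of 2.98, 3.11 and 3.35, in the lowest 9.84, 12.5 and 18 percent of genes.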

How the results depend on the processing

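Centring on the poly-A spike-ins was chosen only after their change had been seen, and all other settings before. Of 357 calls of named genes (of 627 values) 288 held under every setting fixed beforehand that gave a value, each array left out in turn included, and of 29 calls of lists (of 150) 25 did. Without dim genes 16 of the gene calls had no value. Under at least 1 of those settings other than a left-out array 52 gene calls and 2 list calls were lost, without some single array 62 and 3, and with spike-in centring 46 and 0, where another 2 gene calls stood in the opposite direction. Among named genes and lists that were called with or without the setting, no direction turned under any setting but spike-in centring. Turns of values called in neither were not counted. The mean of a gene's probe sets changed no call of these, and neither leaving out cross-hybridising probe sets nor eBayes with trend and robust moved any count of called genes by over 1.5 times. The second deposited table holds the same values and gave no separate result. Detection calls were not used here, so weak signals cannot be told from background; leaving out dim genes moved no count of called genes by over 1.5 times.

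Replicate numbers pair no samples: 23 of 108 same-numbered pairs of arrays had an r over 0.1 (-0.29 to 0.27, median -0.011), in 2 of 36 pairs of groups all 3 did, and 8 of 27 arrays correlated best with their own number. With the replicate block 3719 and 4419 genes were called on days 3 and 6 of the wild type and 28 lists, and no count moved by over 1.5 times. Of named genes PHV on day 6 of the wild type (adjusted p = 0.0551) and between the mutants (0.0555), BBM (upf1-1, day 0; 0.0572) and APL3 (upf3-1, day 0; 0.0578) were not called with the block, nor were the NMD and exon junction factors (upf3-1, day 0; 0.0556), and LAS was called on day 3 of the wild type and in upf1-1 on day 0.

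Some settings move counts by their construction. With a fold minimum, 499 and 636 genes remained on days 3 and 6 of the wild type, 159, 215 and 164 for upf1-1, 169, 300 and 199 for upf3-1 (days 0, 3 and 6), 14 and 32 for the difference of change in upf1-1, 52 and 27 for that in upf3-1 (days 3 and 6), 47, 137 and 17 between the mutants, and 43 higher and 0 lower in both mutants on all days. With all probe sets, which tests more of them, the same counts up to those between the mutants were 7098 and 8412, then 4172, 4243 and 4388, then 3627, 5661 and 4547, then 69 and 145, then 225 and 156, and 1025, 2274 and 632. Without dim genes the covariance of the mutants was 0.0774, 0.0985 and 0.0967 on days 0, 3 and 6, and the reason was not tested.

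For the next settings the cause was not tested. With array weights the difference of change to day 3 was called for 56 genes in upf1-1 and 188 in upf3-1, and 2696 genes differed between the mutants on day 3. With only the groups compared in the fit, which leaves fewer arrays to estimate the variance, 1498 genes were called in upf1-1 on day 6, 1242 in upf3-1 on day 0, 20 and 44 for the difference of change to day 3 in upf1-1 and upf3-1, 409 and 97 between the mutants on days 3 and 6, and 29 were lower in both mutants on all days. With reference gene centring the difference of change to day 3 was called for 21 genes in upf1-1, and genes lower in both mutants numbered 33 on all days and 198, 320 and 238 on days 0, 3 and 6.

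Spike-in centring subtracts the change of the spike-ins from every gene. It gave 12052 genes on day 6 of the wild type, 995 and 1162 on day 6 of upf1-1 and upf3-1, 56 and 26 for the difference of change in upf3-1 to days 3 and 6, 151, 430 and 49 between the mutants, 1367 higher in both mutants on day 0, and 5 lower in both on all days and 18, 54 and 65 lower in both on days 0, 3 and 6. As all genes move alike, a list median can turn while camera, which compares a list with other genes, still calls it. It turned list medians of the NMD and exon junction factors in upf3-1 to 0.027 and 0.061 on days 0 and 3, of the early auxin genes in upf3-1 on day 3 to 0.12, and of NMD targets between the mutants on day 6 to 0.0045. In the wild type it turned AT1G80000 to 0.066 on day 3 and 0.56 on day 6, and on day 6 PDF1.2 to 0.70, YUC4 to 0.54, LAS to 0.30, AUR1 to 0.16, FMA to 0.55, DFR to 0.53, APL3 to 0.33, AT5G15710 to 0.52 and UPF3 to 0.68. In upf3-1 it turned PHV on day 3 to 0.014.

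With 1 array left out in turn, lowest and highest counts were 14 to 38 and 30 to 64 for the difference of change in upf1-1 to days 3 and 6, 48 to 316 and 26 to 98 for that in upf3-1, and 244 to 529, 370 to 1429 and 133 to 317 between the mutants. Genes lower in both mutants numbered 48 to 90 on all days, 216 to 373 on day 0 and 318 to 434 on day 6. Other counts stayed within 1.5 times: 3071 to 3655 and 3651 to 4348 on days 3 and 6 of the wild type, 498 to 556 higher in both mutants on all days, and 26 to 31 lists. Fewer arrays give less power, and where a count rose the cause was not tested.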

Other observations

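The test of plastid-encoded genes was chosen only after the photosynthesis results had been seen. They were tested with camera beside gene families grouped by symbol, 40 sets and 440 tests in all, over which the p-values were adjusted. Of these tests 29 were called at the preset correlation, and 0 were called with an estimated correlation as well. Part of the plastid-encoded genes had a higher signal in upf1-1 than in the wild type. How far these signals follow transcript levels was not tested. Of 69 measured plastid-encoded genes 18, 30 and 19 were called higher on days 0, 3 and 6 and 1, 0 and 0 lower, with medians of 0.25, 0.33 and 0.23. In upf3-1 the medians were 0.06, 0.17 and 0.09, with 6, 14 and 11 called higher and 2, 2 and 0 lower. In the wild type 20 of the 69 were called lower on day 3 and 13 on day 6, and 0 higher, with medians of -0.26 and -0.16 (adjusted p = 0.00137 and 0.128; adjusted p = 0.708 and 0.838 with an estimated correlation). Camera called the plastid list in upf1-1 at the preset correlation (adjusted p = 4.41e-05, 7.08e-09 and 0.000174) and not otherwise (adjusted p = 0.643, 0.573 and 0.679 with an estimated correlation). If plastid and nuclear genes were steered together, they would vary together among replicates: over 27 arrays, deviations from group means correlated with r = 0.0568 (permutation p = 0.802, two-sided; 0.198 without the 2 arrays farthest from the median) and Spearman's rho 0.115 (permutation p = 0.619, two-sided), which cannot tell.

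In all, 61 genes differed between upf3-1 and upf1-1 on all 3 days. AT5G12110, which codes for a translation elongation factor subunit, was higher in upf3-1 by 1.57, 1.71 and 1.73 on days 0, 3 and 6 and the glycosyltransferase gene GT72B1 by 0.54, 0.71 and 0.55, while AT5G52070 was lower (-1.13, -0.80 and -1.18). Among those lower in upf3-1 are 4 genes of a stretch of chromosome 2 that resembles the mitochondrial genome, picked out after the values had been seen: AT2G07695 (-0.46, -0.52 and -0.69), AT2G07741 (-0.83, -0.92 and -0.74), AT2G07749 (-0.70, -0.76 and -0.95) and AT2G07722. Given this resemblance their probe sets may also bind mitochondrial transcripts, so these need not be separate results or changes of the chromosome 2 genes.

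Of 989 transcripts annotated as pseudogenes 11 were higher in both mutants on all days (1.11%), among them AT2G13970, AT3G21020, AT4G08110, AT5G04880 and AT1G64250, and 1 was lower. Loss of NMD could raise such transcripts, as they often carry early stop codons. Sets of 989 protein-coding genes matched for signal gave a median of 6 and a maximum of 17 in 10000 draws, with 0.04 of draws as high (one-sided); of all 12224 protein-coding genes 538 were higher (4.4%). The range of all draws was fixed beforehand as the limit, and since it widens with the number of draws, 11 within it cannot tell.

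Sequence differences linked to the mutations could make genes near UPF3 or UPF1 differ between the mutants. None of the 100 genes nearest to either locus differed on all days (0 of 100 each), beside 60 of 13185 elsewhere (0.455%; Fisher's exact test, adjusted p = 1). At that rate fewer than 1 would be expected near each locus, so this cannot tell.

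Arrays of upf3-1 on day 3 lay at 30.22, 10.82 and 20.32 on the third principal component, and replicate 3 had an array weight of 3.83. The lowest array weight was 0.375, of upf1-1 day 6 replicate 2. The SD of the difference between replicates was 0.17 to 0.28 over groups, with a median of 0.21.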
